A study of Homo sapiens with 6 samples.

How the data were processed

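RNA libraries of 3 parental TPC-1 cultures and 3 TPC-1-Len cultures were compared. Per the labels' protocols, the libraries were poly(A)-selected and strand-specific, the cultures were grown independently and RNA had an integrity number of at least 8. The deposited table has 81456 transcript rows of 16486 Ensembl genes, with 79453 Ensembl transcript identifiers and 2003 identifiers of assembled transcripts. For each library it gives an estimated count and a TPM value per transcript. The authors' estimated counts are not normalized and are whole numbers as deposited; about 100 rows per library hold a count of 0 beside a TPM above 0, so they are treated as rounded estimates. The authors' TPM values are scaled per library, and the deposited rows sum to between 62.6% and 69.4% of the TPM total of a whole library, so the authors scaled over more transcripts than are in this table. The authors also gave a log2 fold change per transcript and a p-value with its adjusted value, from a DESeq2 comparison per the file headers, and marked 17267 rows with 0 counts in all 6 libraries as not tested. The genome build was GRCh38 per the submitters' processing notes; the aligner, the counting program and the annotation release are not given in the sources used here. A transcript's estimated count depends on how reads that several isoforms share were divided, and summing to genes removes most of that dependence. Reads shared between genes, such as histone, HLA and zinc finger paralogs, stay divided as the authors' program divided them. The TPM values were used only to describe the table.

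Library columns were matched to samples by their group and replicate number in the sample titles. Estimated counts were summed per Ensembl gene identifier, which gave 16445 genes with at least 1 count, and library totals of 35629900 to 42281450 counts. Genes with a few counts in a group are given with their counts. Intervals of ratios with few counts are exact binomial intervals at 95% and cover counting error only. Gene positions and types came from the GENCODE 29 annotation of GRCh38, which holds 16424 of the gene identifiers and gives 16338 as protein-coding. CPM values and shares of counts are thus relative to the deposited, mostly protein-coding rows and not to whole libraries. Gene symbols are those of the deposited table; 270 genes had none.

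Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Genes were kept by edgeR's filterByExpr with its defaults (minimum count of 10, minimum total count of 15), libraries were scaled by TMM, and the groups were compared with the quasi-likelihood F test with robust dispersion estimates and group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The common biological coefficient of variation was 0.152. The standard error of a log2 fold change is its size divided by the square root of its F statistic. CPM values (counts scaled to TMM-adjusted library size) were computed here. All adjusted p-values of genes in the report are from edgeR unless the authors' deposited table is named, and those of lists are from limma.

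Before the data were examined, 35 gene lists were fixed: targets of lenvatinib, other receptor kinases, growth factors, pathway targets, metabolism, differentiation and stress lists, markers of endothelial, fibroblast, haematopoietic and thyroid C cells, and 2 lists of RNA quality (mitochondrially encoded genes and histone genes taken to lack a poly(A) tail). The 33 lists with at least 5 tested members were compared with all other genes by camera with its preset correlation of 0.01, with adjustment over the 33 lists; camera with an estimated correlation and fry, which tests a list's own genes only, were alternatives. The number of members called was also counted with adjustment over the list alone. Genes named in the text were chosen by a rule fixed at the same time: the 12 called genes with the largest log2 fold change in each direction among genes with a symbol, a mean count of at least 100 and groups that did not overlap in CPM; every tested lenvatinib target receptor; and, for each other list, up to 4 members with the smallest adjusted p. Genes named outside this rule are said to be so.

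Other alternatives fixed before the data were examined were DESeq2 size factors, upper quartile scaling, library size only, the DESeq2 Wald test, limma-voom, no filter beyond 1 count, a filter at a mean count of 50, the replicate number as a block, an adjusted p under 0.01, a glmTreat test against a 2-fold change, and each library left out in turn. A fit without the 13 mitochondrially encoded genes and PLCG2 was added after the data were seen. PLCG2 took between 1.16% and 1.85% of the counts of every library, and replication-dependent histone genes took 1.39% to 3.77%, high shares for poly(A)-selected RNA; whether another enrichment was used is not given in the sources used here. Terms of the deposited gene annotation with 10 to 300 tested genes were tested with camera, also after the data were seen.

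The tests were tried on simulated counts with the means, dispersions and library sizes of this comparison. Of the 13226 genes of the main fit, 200 were changed and a separate list of 30 was raised. In the simulated counts 13125 genes passed the filter and were tested. Of 50 genes changed at each size, the edgeR test called 28% at 1.5-fold, 82% at 2-fold, 98% at 4-fold and 96% at 8-fold, and 6.90% of the genes it called had not been changed. Camera called the list of 30 genes, raised by 0.6 on the log2 scale, and 0 of 32 unchanged lists. The simulated genes varied independently, so the simulation does not test camera where genes are correlated. Far fewer genes were changed in it than the 44.9% called in the data, and the Benjamini-Hochberg threshold depends on that share. The shares recovered therefore do not give the power of the real comparison. The second deposited sheet repeats transcripts of the first with a p-value under 0.01 and was not used.

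One of the 12 genes with the largest rise and one member of the histone list are not reported by name here; both stay in the counts of genes and lists.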

Results

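RNA was sequenced from 6 cultures of TPC-1, a human papillary thyroid carcinoma cell line that carries a CCDC6-RET fusion. Parental cells (3 cultures) were compared with TPC-1-Len cells (3 cultures), a subline selected by continuous growth in 6 µM lenvatinib for more than 3 months and harvested without the drug. Lenvatinib is an oral inhibitor of the VEGF and FGF receptors, the PDGF receptor alpha (PDGFRA), KIT and RET. Gene counts summed to between 35629900 and 42281450 per library, and 14958 to 15149 genes had at least 1 count in a library. Replicates of a group resembled each other more (Pearson r across genes of 0.981 to 0.993 for log2 CPM, the counts scaled to library size) than libraries of different groups did (0.926 to 0.950); these values are across genes, which are not independent replicates. The first principal component, with 77.8% of the variance, separated the groups, and the second, with 11.8%, set parental replicate 2 apart from the other parental libraries. Mitochondrially encoded genes took 11.8% of the counts in parental replicate 1 and between 5.15% and 7.39% in the other 5 libraries.

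The comparison asked how the transcriptome of cells that grow in lenvatinib differs from that of the cells they came from. Most of the genes with the largest rises were interferon-stimulated. RSAD2 (ENSG00000134321), which encodes the antiviral enzyme viperin, went from 0.0326 ± 0.0357 to 19.9 ± 1.51 CPM (mean ± SD, n = 3 each), IFI27 (ENSG00000165949) from 0.297 ± 0.167 to 94.0 ± 4.57, and OAS2 (ENSG00000111335), an oligoadenylate synthetase, from 1.04 ± 0.105 to 129 ± 3.40. IFI44L, CMPK2, OASL, IFIT1, OAS1, IFI44 and IFIT3 followed, with log2 fold changes between 4.47 (IFIT3, SE 0.17) and 7.38 (IFI44L, SE 0.33). The genes with the largest rises also held the semaphorin co-receptor gene PLXNA4 (log2 fold change 5.24, SE 0.24). Adjusted p for these 11 lay between 1.06e-09 (OAS2) and 6.42e-07 (IFI44).

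The largest falls came from genes that were nearly silent in TPC-1-Len cells. PDPN (ENSG00000162493), which encodes the membrane glycoprotein podoplanin, had 604, 510 and 571 counts in the parental libraries and 2, 4 and 0 in the TPC-1-Len libraries (log2 fold change -8.12, SE 0.38, edgeR adjusted p = 1.39e-07). RELN (reelin, an extracellular matrix glycoprotein) fell from 139 ± 19.2 to 2.23 ± 0.203 CPM, BGN (the proteoglycan biglycan) from 131 ± 25.5 to 2.57 ± 0.186, and ELF3 (an epithelial transcription factor) from 126 ± 15.3 to 3.30 ± 0.168. MACROH2A2, a variant histone gene, had 189, 198 and 213 counts in the parental libraries and 2, 0 and 0 in the TPC-1-Len libraries, a ratio of 315 with a 95% counting interval of 86.8 to 2606. H4C6, a histone H4 gene, fell from 22.3 ± 6.16 to 0.0637 ± 0.0639 CPM; its coding sequence is close to that of other H4 genes, so its count is uncertain. The sphingosine-1-phosphate transporter gene SPNS2 (log2 fold change -6.47, SE 0.24), ZNF518B (-6.91, SE 0.35), PDZK1IP1 (-6.26, SE 0.32), ZNF160 (-5.71, SE 0.27), SOWAHD (-5.55, SE 0.31) and the prothrombin gene F2 (-5.29, SE 0.28) completed the 12.

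On the GRCh38 assembly, RSAD2 lies on chromosome 2 (6865806 to 6898239), IFI27 on chromosome 14 (94104836 to 94116698), OAS2 on chromosome 12 (112978395 to 113011723), PDPN on chromosome 1 (13583465 to 13617957), MACROH2A2 on chromosome 10 (70052796 to 70112280) and H4C6 on chromosome 6 (26240426 to 26240737). The annotation gives each of these 23 genes as a protein-coding gene, and its counts are sums over the authors' transcript rows of that gene.

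Of 13226 genes tested, 5942 (44.9%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2921 higher and 3021 lower in TPC-1-Len cells. Among them 1996 changed at least 2-fold, 751 higher and 1245 lower. With library size as the only scaling, the share of higher genes among those called was 61.4% in place of 49.2%, since that scaling moved the median log2 fold change of all genes from 0.01 to 0.14. A test against a 2-fold change itself (glmTreat) called 835 genes. The 3 cultures of each group came from 1 parental line and 1 resistant subline, so the p-values measure the spread between cultures and not between independently derived resistant lines.

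**Figure D1:**
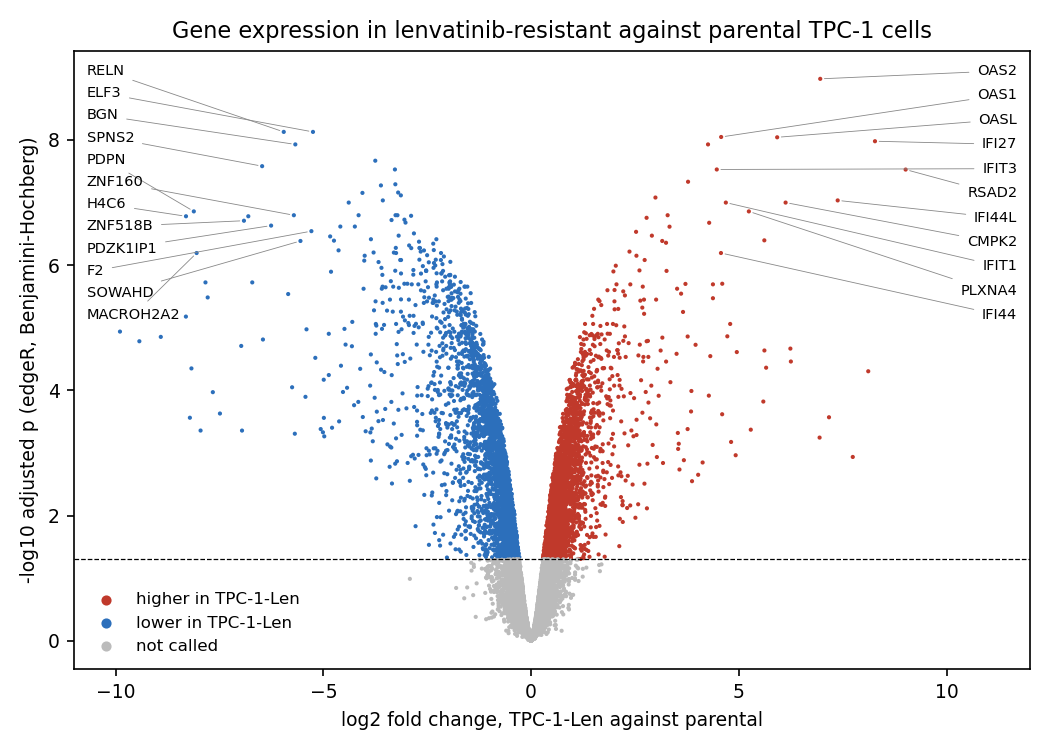
Log2 fold change (x axis, TPC-1-Len against parental) and -log10 adjusted p (y axis) of the 13226 genes tested, 3 libraries per group. Red points were higher and blue points lower at an adjusted p under 0.05 (dashed line), and the labelled genes are 11 of the 12 with the largest rise and the 12 with the largest fall under the naming rule.

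Among the receptors that lenvatinib inhibits, all 4 FGF receptors were lower in TPC-1-Len cells. FGFR1, the most abundant of them, fell from 244 ± 25.2 to 129 ± 14.4 CPM (log2 fold change -0.92, SE 0.13, adjusted p = 0.000243), and FGFR2 from 13.8 ± 0.901 to 4.97 ± 0.277 (-1.47, SE 0.15, 2.41e-05). FGFR3 changed by -0.75 (SE 0.21, 0.0124) and FGFR4 by -0.57 (SE 0.18, 0.0241). RET had 40.9 ± 1.21 CPM in parental and 36.4 ± 1.49 in TPC-1-Len cells (-0.17, SE 0.11, adjusted p = 0.244); gene counts do not separate reads of the fusion from those of intact RET. FLT1, FLT4 and PDGFRA had at most 9 counts in any library and were not tested, and KDR and KIT had no row in the table used here. Thus 4 of the 5 tested receptors were called over all genes, and 4 adjusted over the list alone. PDGFRB was not in this list and is given with the other receptor kinases. FGFR1 lies on chromosome 8 (38400215 to 38468834), FGFR2 on chromosome 10 (121478334 to 121598458) and RET on chromosome 10 (43077027 to 43130351). As a list the receptors were lower (camera adjusted p = 0.0425), but not with an estimated correlation (adjusted p = 0.438). The list's call was lost without parental replicate 2 (adjusted p = 0.0611), parental replicate 3 (0.0545), TPC-1-Len replicate 2 (0.0559) or TPC-1-Len replicate 3 (0.057), with no low count filter (0.143) and with the replicate number as a block (0.0521). FGFR3 lost its call without TPC-1-Len replicate 3 (0.0612) and FGFR4 without TPC-1-Len replicate 2 (0.0799) or 3 (0.111) and with library size as the only scaling (0.0576), so that 2 receptors were called without TPC-1-Len replicate 3.

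Other receptor tyrosine kinases were also lower on balance. Of 24 tested, 12 fell and 3 rose (15 called adjusted over the list alone). EPHA4 (log2 fold change -1.98, SE 0.14), PDGFRB (-1.75, SE 0.13), IGF1R (-1.53, SE 0.14) and INSR (-1.44, SE 0.13) had the smallest adjusted p. EGFR, named after its values were seen, changed by -1.04 (adjusted p = 0.000127), while MET (0.03, adjusted p = 0.862) and AXL (0.14, adjusted p = 0.387), also named afterwards, did not pass the test. The list was called (camera adjusted p = 0.00343; adjusted p = 0.462 with an estimated correlation). Of 26 growth factor ligand genes, 7 rose and 8 fell (16 adjusted over the list alone), among them PDGFB (-4.82, SE 0.32), HBEGF (2.62, SE 0.25), FGF1 (1.54, SE 0.18) and NRG2 (1.30, SE 0.17); the list was not called (0.981). Targets and feedback genes of the ERK pathway moved both ways. Of 24 genes, 8 rose, including the feedback inhibitor SPRY4 (2.01, SE 0.16) and the cyclin D1 gene CCND1 (1.49, SE 0.13), and 8 fell, including EPHA4 and EGR1 (-1.55, SE 0.14), with 17 called adjusted over the list alone and no call for the list (0.65). The immediate early and heat shock list moved both ways, with NR4A1 (-1.98, SE 0.14), EGR1 and EGR2 (-2.13, SE 0.22) lower and the chaperone gene HSPH1 (2.05, SE 0.18) higher. Of its members, 7 of 18 rose and 10 fell, and all 18 were called adjusted over the list alone, while the list itself was not (0.65). It joins immediate early genes with heat shock genes, and opposite moves of these cancel in a list test. Named afterwards, HSPA8 was also higher (1.26, adjusted p = 4.89e-05) and HSPB1 lower in CPM without overlap. The deposited annotation's term for regulation of cellular response to heat had 29 of 46 genes higher and 0 lower. Its camera adjusted p, from a test added afterwards, was 0.000417 (0.832 with an estimated correlation).

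All 35 tested members of the interferon response list rose, over all genes and adjusted over the list alone, with a median log2 fold change of 3.01. OAS2, OAS1 (4.57, SE 0.14), OASL (5.92, SE 0.18) and IFI27 (8.28, SE 0.26) had the smallest adjusted p. This was the list with the smallest camera p (adjusted p = 2.34e-84) and the only list called with an estimated correlation (adjusted p = 0.00643). Among 19 antigen presentation genes, 11 rose and 5 fell (17 adjusted over the list alone). The peptide transporter genes TAP1 (1.44, SE 0.15) and TAP2 (1.15, SE 0.13) and the class I gene HLA-B (1.09, SE 0.12), which has close paralogs, were higher, and CD74, the class II invariant chain, fell from 2.48 ± 0.479 to 0.209 ± 0.0384 CPM. The mean log2 fold change of these 19 genes was 0.06 (SD 1.51 across members) beside a median of 0.47. The antigen presentation list passed (camera adjusted p = 0.0453; adjusted p = 0.524 with an estimated correlation) but not without parental replicate 1 (0.0565), parental replicate 3 (0.0958), TPC-1-Len replicate 1 (0.112) or TPC-1-Len replicate 2 (0.118), nor in limma-voom (0.0562), with no low count filter (0.0984) or with the replicate block (0.0521). NF-kB-associated inflammatory genes were lower, with 10 of 23 lower and 4 higher (16 adjusted over the list alone, camera adjusted p = 0.00746; adjusted p = 0.462 with an estimated correlation). The complement gene C3 (-4.39, SE 0.20), ICAM1 (-2.70, SE 0.15), CCL2 (-2.84, SE 0.19) and SAA1 (-3.74, SE 0.32) led these falls. In limma-voom this list's adjusted p was 0.0664.

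**Figure D2:**
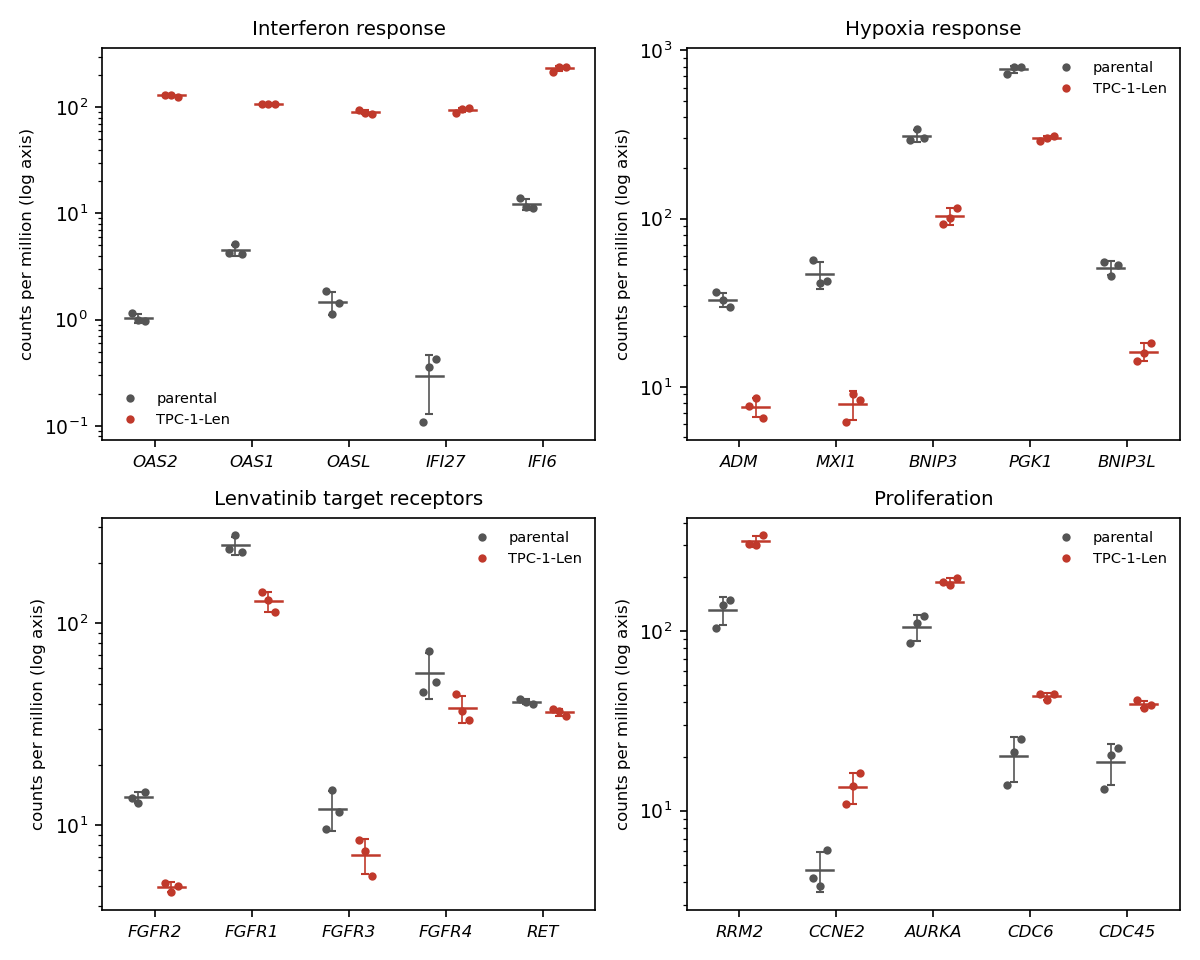
CPM (log axis) in each library for the 5 members with the smallest adjusted p of 4 gene lists. Points are libraries, horizontal lines are means and error bars are SD (n = 3); OAS2, OAS1, OASL, IFI27 and IFI6 did not overlap between the groups, and RET had the smallest difference among the receptors.

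Genes of the hypoxia response were lower in TPC-1-Len cells. Of 29 tested, 22 fell and 0 rose (23 adjusted over the list alone), and the 7 others did not pass. The falls included ADM (adrenomedullin, log2 fold change -2.12, SE 0.15), MXI1 (-2.57, SE 0.19), the mitophagy receptor gene BNIP3 (-1.59, SE 0.13), and the glycolytic gene PGK1, which went from 771 ± 39.7 to 301 ± 9.90 CPM. LDHA (-1.18) and VEGFA (-0.79), named after their values were seen, were also called. The list's adjusted p was 8.45e-11 in camera and 0.0975 with an estimated correlation.

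Lipid genes were lower on balance. The counts of called members stand beside 44.9% called over all tested genes, of which 49.2% were higher. In the cholesterol synthesis list 13 of 23 fell and 1 rose (14 adjusted over the list alone), led by SREBF2, the regulator of the pathway (-1.22, SE 0.13), TM7SF2 (-1.77, SE 0.19), DHCR7 (-1.01, SE 0.14) and SQLE (-0.67, SE 0.11). In the fatty acid list 7 of 20 fell and 1 rose (8 adjusted over the list alone), with the desaturase gene SCD (-2.10, SE 0.13) and ACSS2 (-1.93, SE 0.14) lower and FABP5 (1.23, SE 0.14) higher. Camera gave adjusted p of 0.0293 for cholesterol and 0.0425 for fatty acids, each with an adjusted p of 0.365 with an estimated correlation. Cholesterol synthesis lost its call without parental replicate 3 (0.0514), and the fatty acid list without parental replicate 3 (0.058), TPC-1-Len replicate 1 (0.0553) or TPC-1-Len replicate 2 (0.0559) and with the replicate block (0.0521). In the amino acid response list, 10 of 32 genes fell and 2 rose (12 adjusted over the list alone, camera adjusted p = 0.0282; adjusted p = 0.438 with an estimated correlation), among them CHAC1 (-1.71, SE 0.14), DDIT4 (-1.47, SE 0.13) and PCK2 (-1.18, SE 0.11), with WARS1, also an interferon-inducible gene, higher (0.86, SE 0.11). The 20 other genes of the amino acid response list were not called, and the list's median log2 fold change was -0.18. Endoplasmic reticulum chaperone genes went the other way: 9 of 21 rose and 2 fell (11 adjusted over the list alone), with MANF (1.13, SE 0.13) and HYOU1 (1.11, SE 0.13) higher and HERPUD1 (-1.57, SE 0.14) lower. That list passed at an adjusted p of 0.0425 (adjusted p = 0.438 with an estimated correlation) and not without parental replicate 3 (0.0545), TPC-1-Len replicate 1 (0.0606) or TPC-1-Len replicate 2 (0.0594), nor with the replicate block (0.0521).

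Cell cycle genes were higher. Of 38 proliferation genes, 31 rose and 0 fell (34 adjusted over the list alone), with a median log2 fold change of 0.66. RRM2, a ribonucleotide reductase subunit gene, rose from 131 ± 23.1 to 314 ± 21.6 CPM, and CCNE2 (1.53, SE 0.21), AURKA (0.83, SE 0.14) and CDC6 (1.11, SE 0.19) rose too. The list's adjusted p was 5.95e-07 in camera and 0.473 with an estimated correlation. Of 12 histone genes listed beforehand as lacking a poly(A) tail, 6 rose and 1 fell (7 adjusted over the list alone), with H2BC21 (0.87, SE 0.14) and H2BC12 (0.69, SE 0.16) higher. Whether the transcripts counted had tails was not measured, so the list does not by itself show how libraries were prepared. Its mean log2 fold change was 0.19 (SD 2.00 across members) beside a median of 0.43. The histone list did not pass (0.0512), but did without parental replicate 2 (0.0106) or TPC-1-Len replicate 2 (0.0179), with upper quartile scaling (0.0373), library size only (0.0423), limma-voom (0.0217), no low count filter (0.0273) and a filter at a mean count of 50 (0.0463). Its call thus depends on the processing. Among 25 p53 targets 11 rose and 4 fell (17 adjusted over the list alone), with AEN (1.49, SE 0.14), PMAIP1 (1.86, SE 0.19) and TIGAR (1.99, SE 0.21) higher and TP53INP1 (-1.39, SE 0.17) lower; the list was not called (0.0696), but was without parental replicate 2 (0.0454) and by fry (0.000462). Of 23 apoptosis regulators 9 rose and 6 fell (15 adjusted over the list alone, list adjusted p = 0.439, in fry 0.00453), including BMF (-3.05, SE 0.21) and BAK1 (0.92, SE 0.16).

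Matrix and mesenchymal genes were lower on balance, with 14 of 25 lower and 5 higher (19 adjusted over the list alone, camera adjusted p = 9.17e-05; adjusted p = 0.438 with an estimated correlation). The lysyl oxidase gene LOX (-4.06, SE 0.17), TGFBI (-3.57, SE 0.16), SPARC (-1.72, SE 0.13) and COL4A1 (-1.52, SE 0.12) fell. Of 21 YAP/TAZ targets 12 fell and 1 rose (13 adjusted over the list alone, camera adjusted p = 4.35e-05; adjusted p = 0.365 with an estimated correlation). IGFBP3 (-2.28, SE 0.12), NUAK2 (-2.16, SE 0.14) and TGFB2 (-2.46, SE 0.19) fell, and NT5E, which encodes the ecto-5'-nucleotidase, was the member that rose (2.99, SE 0.13). TGF-beta targets (3 of 22 higher, 9 lower, 12 adjusted over the list alone) did not pass as a list (0.0746), but did without parental replicate 1 (0.0308), with a filter at a mean count of 50 (0.0491) and in fry (0.00489), and shared TGFBI and TGFB2 with the lists above. Epithelial genes did not pass either (3 of 18 higher, 6 lower, 10 adjusted over the list alone, 0.0746, in fry 0.00818), with JUP (-2.31, SE 0.15) and TJP3 (-3.58, SE 0.24) lower and LAMB3 (1.18, SE 0.14) higher. Among 10 thyroid differentiation genes 4 fell and 1 rose (5 adjusted over the list alone, list adjusted p = 0.0969, 0.0491 with a filter at a mean count of 50 and 0.00818 in fry): the transcription factor genes GLIS3 (-1.83, SE 0.13) and FOXE1 (-1.13, SE 0.15) and the receptor gene THRB (-0.94, SE 0.16) fell, and HHEX (0.78, SE 0.16) rose.

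Drug efflux transporter genes were lower, with 11 of 17 lower and 0 higher (11 adjusted over the list alone, camera adjusted p = 0.000296; adjusted p = 0.365 with an estimated correlation). ABCC3 fell by 3.02 on the log2 scale (SE 0.15), ABCB1, which encodes P-glycoprotein, by 3.09 (SE 0.32), ABCA1 by 1.59 (SE 0.13) and ABCA2 by 1.18 (SE 0.14). Of 14 drug metabolism genes 7 fell and 2 rose (9 adjusted over the list alone, list adjusted p = 0.158, in fry 0.00439), with ALDH1A3 (-1.35, SE 0.12) lower and AOX1 (1.16, SE 0.17) and CYP1A1 (1.33, SE 0.22) higher. Of 27 NRF2 targets 7 rose and 5 fell (12 adjusted over the list alone, 0.743), with GCLM (1.15, SE 0.16) higher and FTL (-1.03, SE 0.12) lower; the median of this list was -0.03 while its mean, 0.09, and its test pointed up. Ferroptosis genes (4 of 19 higher, 7 lower, 12 adjusted over the list alone, 0.391, in fry 0.00448) included CHAC1 and FTL, and autophagy and lysosome genes (4 of 28 higher, 8 lower, 12 adjusted over the list alone, 0.415, in fry 0.0142) included GABARAPL1 (-1.42, SE 0.14) and CTSL (1.03, SE 0.11). The Notch list (1 of 13 higher, 5 lower, 7 adjusted over the list alone, 0.0969) had NOTCH3 (-2.61, SE 0.17) lower and HEY1 (2.41, SE 0.37) higher, and passed without parental replicate 1 (0.0308) or with a filter at a mean count of 50 (0.0375). Wnt targets (6 of 13 higher, 3 lower, 9 adjusted over the list alone, 0.65) and stem cell genes (3 of 8 higher, 2 lower, 5 adjusted over the list alone, 0.906) were not called; LGR5, in both, rose (2.82, SE 0.29).

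**Figure D3:**
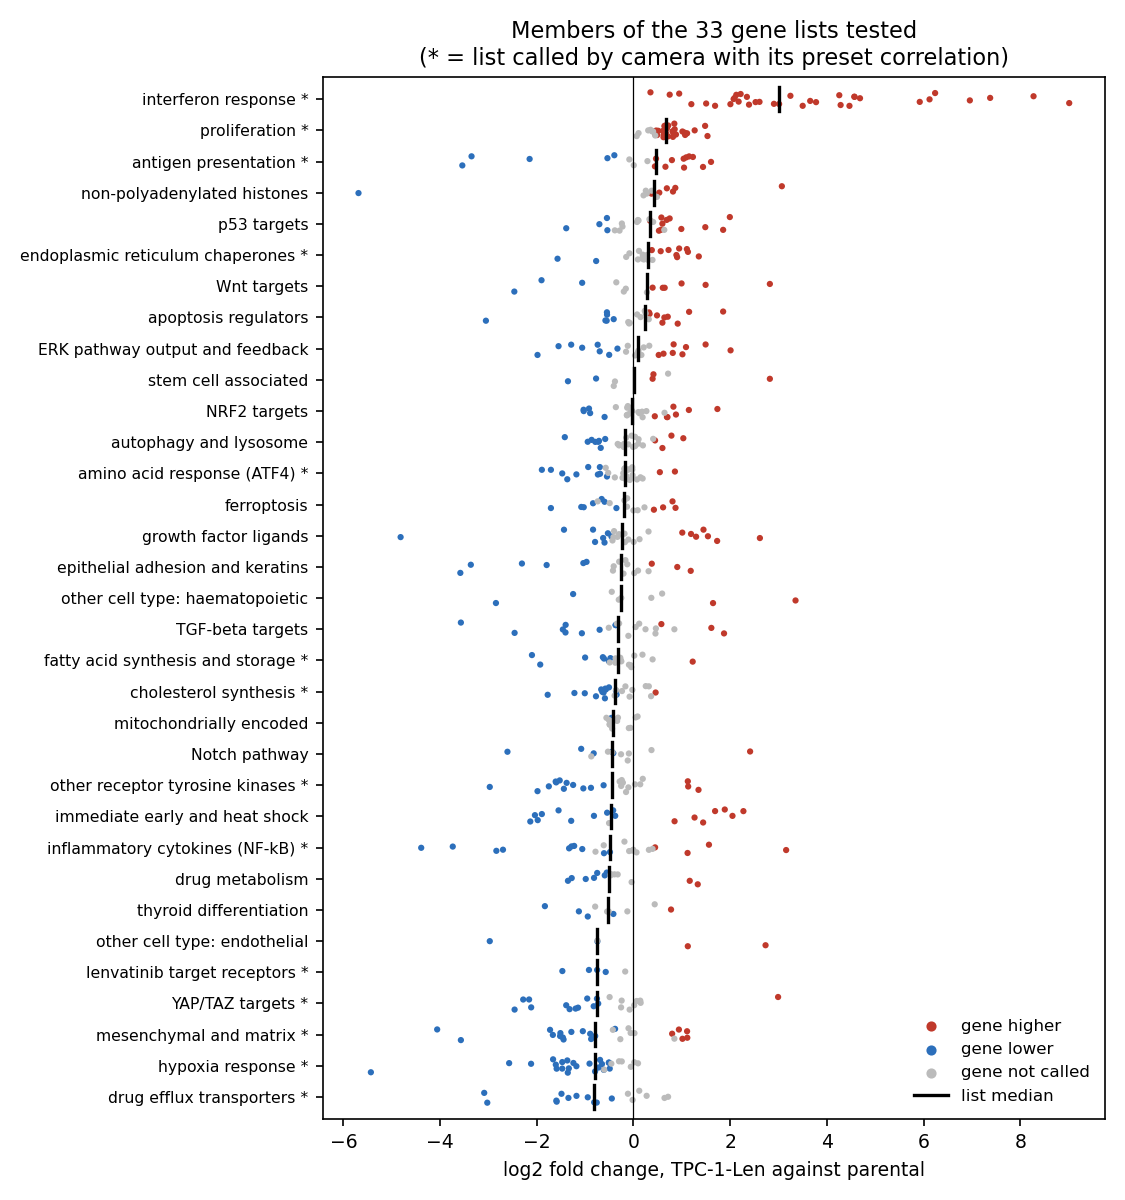
Log2 fold change (x axis, TPC-1-Len against parental) of each tested member of the 33 gene lists with at least 5 tested members, ordered by list median (black bars). Red members were higher and blue members lower in the gene-level test, and an asterisk marks the 14 lists called by camera with its preset correlation, of which interferon response alone passed with an estimated correlation.

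Markers of other cell types moved both ways. Of 9 haematopoietic genes tested, LCP1 and ITGB2 rose to 2.40 ± 0.613 and 3.15 ± 0.389 CPM, CD14 and CSF1R fell, and 5 were called adjusted over the list alone (list adjusted p = 0.65, median -0.25, mean 0.10, test direction up); the CSF1R call was lost without TPC-1-Len replicate 3 (0.0529). Of 5 endothelial genes ROBO4 (2.73, SE 0.17) and TIE1 rose and TEK (-2.97, SE 0.56) and ERG fell (4 adjusted over the list alone, list adjusted p = 0.543, in fry 0.00457, median -0.74 and test direction up), with ERG losing its call without parental replicate 1 (0.0582) or TPC-1-Len replicate 1 (0.0876) and with library size only (0.0574). The fibroblast list had 4 tested genes, too few for the list test: PDGFRB, COL1A1 (-1.46, SE 0.18) and THY1 fell and TWIST2 (1.11, SE 0.15) rose (4 adjusted over the list alone). Of 3 thyroid C cell genes tested, GFRA1 fell (-1.13, SE 0.12) and SYP and RET did not pass (2 adjusted over the list alone). SYP was called higher with upper quartile scaling (0.0491), with library size only (0.0256), without TPC-1-Len replicate 3 (0.0439) and without the mitochondrially encoded genes and PLCG2 (0.045). Among 13 mitochondrially encoded genes 0 rose and 1 fell, MT-CO3 (-0.46, SE 0.16, adjusted p = 0.0333), and 0 were called adjusted over the list alone (list adjusted p = 0.65). MT-CO3 lost its call without parental replicate 1 (0.12), TPC-1-Len replicate 2 (0.0956) or TPC-1-Len replicate 3 (0.134) and with library size only (0.0702). MT-CO1 was called lower without parental replicate 2 (-0.59, adjusted p = 0.0284).

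In total, 14 of the 33 lists were called, 4 higher and 10 lower, in a test that assumes a fixed small correlation between genes; with an estimated correlation 1 list was called. Without parental replicate 3, 9 lists were called.

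The authors' deposited table compared transcripts, not genes. It called 4459 transcripts of 3227 genes, 2044 higher and 2415 lower in TPC-1-Len cells. Each had an absolute log2 fold change of at least 1. Of the 3131 genes whose called transcripts there all moved 1 way, 2504 were called in the same direction by the gene-level test here, 54 in the opposite direction, 563 were not called and 10 were not tested. Conversely, 3332 of the genes called here had no transcript called there, 385 of them changed at least 2-fold. In 96 genes the authors' deposited table called transcripts in both directions.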

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

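No named gene changed direction in a setting that gave it a value, and of the 143 named genes called, 6 lost their call in at least 1 setting (CD44, CSF1R, ERG, FGFR3, FGFR4 and MT-CO3). Between 4464 and 6997 genes were called with a library left out (2085 to 3689 higher, 2351 to 3308 lower, 1772 to 2212 at least 2-fold). At an adjusted p under 0.01, 3929 genes were called, 1764 of them higher, and 2 receptors; a stricter threshold calls fewer genes by construction. The glmTreat test called 835 genes in place of 1996, since it asks for more than a 2-fold change. Between 2 and 4 receptors were called with a library left out, the fewest without TPC-1-Len replicate 3. Scaling by library size alone raised the median log2 fold change of all genes to 0.14 and the share of higher genes to 61.4%.

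The number of gene lists called depended most on the test: 14 with camera's preset correlation, 1 with an estimated correlation, 23 with fry, and 9 to 15 with a library left out. The fry test asks only whether a list's own genes move, and the estimated correlation widens the null distribution; the cause of the lower count without parental replicate 3 was not tested.

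Replicate numbers did not pair the samples: the correlation of deviations from the group means was -0.24 for number 1, -0.10 for number 2 and 0.32 for number 3, and parental replicate 2 correlated best with TPC-1-Len replicate 1 (0.44). With the number as a replicate block, 5742 genes were called (2872 higher, 2870 lower, 2053 at least 2-fold), with 4 receptors and 10 lists; the receptor, antigen presentation, fatty acid and endoplasmic reticulum chaperone lists lost their calls. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05, and what this test would show was written down after its counts had been seen. The real split, 1 of the 10, gave 5942 genes (2921 higher, 3021 lower, 1996 at least 2-fold) and 4 receptors, and the highest of the others 0 in each case. Every other split put cultures of both lines in each group, so the difference between the lines added to the spread within groups. The 0 was thus largely set by the design, and nothing is concluded from it. For lists the real split gave 14 and the others 6 to 10, so that camera with its preset correlation also called lists where the groups were mixed. Why it did so was not tested, and a part of the group difference remains in every mixed split.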

Other observations

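Terms of the deposited gene annotation, a test chosen after the data were seen, added groups, some of which share genes with the fixed lists. Of 1542 terms, 67 were higher and 35 lower in TPC-1-Len cells (camera, preset correlation), and 0 passed with an estimated correlation (lowest adjusted p = 0.504, for the type I interferon signaling pathway, with 20 of 32 genes higher and 4 lower). Ribosome biogenesis genes were higher, with 62 of 97 higher and 4 lower (median log2 fold change 0.54, adjusted p = 3.45e-07; adjusted p = 0.832 with an estimated correlation). Mitochondrial translational termination (48 of 94 higher, 1 lower, adjusted p = 0.000315) and RNA splicing (118 of 274 higher, 11 lower, adjusted p = 0.000319) were also higher. Extracellular matrix organization (67 of 132 lower, 18 higher, adjusted p = 1.34e-07), cell adhesion (136 of 300 lower, 43 higher, adjusted p = 0.00013) and glycosaminoglycan catabolism (14 of 20 lower, 1 higher, adjusted p = 0.00406) were lower; each of these 5 also had an adjusted p of 0.832 with an estimated correlation.

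In some genes transcripts moved in opposite directions. Among genes with transcripts called in both directions in the authors' deposited table, those with the highest counts, a rule set after the data were seen, included PTGES3, CD44 and UBAP2L. The UBAP2L transcript ENST00000343815 had 61.1 ± 18.3 CPM in parental and 153 ± 16.2 in TPC-1-Len libraries (SD, n = 3), ENST00000428595 had 31.3 ± 29.4 and 9.62 ± 0.283, and the gene's total changed by 0.06 on the log2 scale (adjusted p = 0.669). The CD44 transcript ENST00000433892 went from 46.6 ± 5.37 to 94.7 ± 13.4 and ENST00000279452 from 30.2 ± 22.8 to 10.3 ± 3.60. The totals of CD44 (0.40, adjusted p = 0.0215) and PTGES3 (0.48, adjusted p = 0.00775) were higher, but CD44 was not called without parental replicate 3 (0.0577), TPC-1-Len replicate 1 (0.0697) or TPC-1-Len replicate 2 (0.0853). Estimated counts of isoforms that share exons are less certain than gene totals, and the parental libraries spread widely for the falling transcripts.

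Of the tests below, the one on leukocyte RNA and those on histone genes were chosen after the result was seen. The interferon response was higher in TPC-1-Len cells, and 2 technical explanations were set against it. RNA from leukocytes would bring their abundant transcripts: LCP1 (3.35) and ITGB2 (1.65) rose, but CD14 fell (-2.84) and PTPRC had 2 counts in the 3 TPC-1-Len libraries together (upper bound of the 95% counting interval 7.22) and 2 in the parental ones, against 2362 of RSAD2 in TPC-1-Len libraries, which argues against it. The change did not come from 1 library either, since at least 34 list members were called higher with any library left out. Among interferon genes, looked up after the data were seen, 2 were counted in every TPC-1-Len library and in no parental one. IFNL1 had 16, 17 and 22 counts (17.5-fold over a floor of 3 counts for the parental group) and IFNB1 had 4, 9 and 8 (6.67-fold over that floor). These ratios leave out the counting error of the TPC-1-Len counts and are not lower bounds. In the edgeR test IFNL1 was called higher (log2 fold change 7.17, SE 0.90, adjusted p = 0.000269), a size that rests on 0 parental counts. IFNB1 had too few counts to be tested. IFNE went the other way, with 3, 2 and 3 counts in parental and 0, 1 and 1 in TPC-1-Len libraries. Looked up at the same time, SOCS3 (-0.97, adjusted p = 0.000205) and JAK1 (-0.75, adjusted p = 0.000459) were lower and SOCS1 did not pass (-0.01, adjusted p = 0.976). Whether the resistant subline makes interferon was not tested, nor whether the lenvatinib selection or another event in this 1 subline, such as an infection, started the response.

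The 25 genes with a mean count of at least 100 and a log2 fold change of -4 or lower in TPC-1-Len cells include ELF3, RELN and PDPN. Deletions that span neighbouring genes are argued against for the set. The nearest tested genes on each side within 500 kb (46 flanking positions) had a median log2 fold change of -0.013 (95% bootstrap interval -0.34 to 0.26). Of the 25, 0 lay directly next to another. BGN and DUSP9, both in the set, shared the neighbour between them, which changed by 1.02 and was counted for both. Reads moved to an overlapping gene were possible for 12% of them, the share that overlapped a gene called higher. Only 7 of the 25 overlapped any tested gene, so this share could not be large. Reads moved to a similar gene elsewhere, as is possible for H4C6 and the zinc finger genes in the set, were not tested. Deletions of single genes, and larger ones at a few loci (a neighbour of SPNS2 changed by -4.58), remain open, as does silencing, which may differ between the lines and was not tested here.

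Replication-dependent histone genes, 58 in all, rose together: 50 were called higher and 1 lower (H4C6), and they took 1.39%, 2.23% and 1.88% of the counts in parental and 3.45%, 2.97% and 3.77% in TPC-1-Len libraries. Reads shared between near-identical copies would leave the sum unchanged, but the summed CPM rose by a ratio of 1.69 without overlap between the groups. A copy gain of the cluster on chromosome 6 (26020490 to 27893843) is argued against by the 9 histone genes on other chromosomes, with a median log2 fold change of 0.87, and by 13 other genes inside the cluster, with a median of 0.00. Most of these mRNAs lack a poly(A) tail, so a larger carry-over of such RNA into the TPC-1-Len libraries (median log2 fold change 0.81) cannot be told apart from more cells in S phase, since no other class of RNA without a tail is in the table. The rise of the proliferation genes, which have tails, is consistent with the latter and does not exclude the former.

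Over 1198 windows of 40 neighbouring genes on the autosomes, 6 had a median beyond the 95th percentile of the largest shift in 100 permutations of gene order (0.487). Windows started every 10 genes and so shared genes, and the 6 need not be separate regions. Histone genes were kept in the windows, and whether their cluster gave any of the 6 was not tested.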
